A study of Danio rerio with 10 samples.

How the data were processed

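Gene expression was measured in whole zebrafish embryos at 72 h after fertilization with a 1-colour Affymetrix GeneChip array for zebrafish, on which each transcript is read by a set of short probes. Per the labels' protocols, fertilized eggs at the 1- to 2-cell stage were injected with 1 to 2 nL of morpholino at 130 micromol/L, total RNA was purified on silica columns, and the RNA was labelled with biotin. A morpholino is a synthetic antisense oligonucleotide that blocks translation or splicing of its target transcript. The 10 arrays fell into 4 groups by their titles: 3 of control morphants, 3 of Atg7 morphants, 3 of embryos injected with both the Atg7 and the Bdh2 morpholino (called dual morphants here) and 1 of Bdh2 morphants. The same 130 micromol/L is listed for single and dual injections. Whether it held for each morpholino or for their sum was not settled here. Nothing in the labels says that the replicates came from separate clutches, so the p-values measure the spread between these samples, which may be technical.

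The deposited values were log2 intensities summarised by the authors to 1 value per probe set, with Affymetrix Expression Console named in the submitters' processing notes. The summarisation algorithm, the background correction and the normalization were not given in the sources used here. That the values are log2 was read from their range, 2.48 to 14.9, and the array medians lay between 6.32 and 6.38, so the arrays had been brought to a common level before deposit. Such a step would hide a change of all transcripts in the same direction, and a summary over probes can compress large differences near background. No detection calls were used, and for arrays the number of samples limits the precision.

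The table held 15617 probe sets. The 115 AFFX control probe sets were left out of the tests, and 15502 were tested. The platform annotation listed 1 gene symbol for 10795 of them, several for 135 and none for 4572. Of the probe sets with a symbol, 10711 had an Entrez ID found in the RefSeq gene table of the GRCz12tu assembly, which was used for current symbols and for the order of genes along chromosomes, and no coordinate was taken from it. Probe sets with several symbols were not named, and those with none are unnamed here. The named probe sets stood for 8793 genes, of which 1539 had more than 1 probe set. Of the tested probe sets, 917 carry a suffix (s_at, x_at or a_at) that marks probes shared with other transcripts; among the genes named in the text these are irf1b, fosab, mmp13a, hbae3, hsp70.3, cyp17a1, cryba4, rrm1, mpx and col1a1a.

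All 10 arrays were fitted together, with 4 groups and 6 residual degrees of freedom, using lmFit and eBayes of limma 3.58.1 in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over the 15502 probe sets with a threshold of 0.05. The fit lends the spread of the other groups to the lone Bdh2 array, so every comparison with that array assumes that it varies as they do and has no replicate check. The comparisons were Atg7 minus control, dual minus control, dual minus Atg7, Bdh2 minus control, dual minus Bdh2, and the departure from additivity on the log2 scale (dual minus Atg7 minus Bdh2 plus control). Errors beside log2 differences are standard errors from this fit unless SD is written.

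The groups, comparisons, tests, 40 gene lists and the rule for named genes were fixed before the data were examined. Named genes are bdh2, then the 10 largest rises and 10 largest falls per comparison of triplicate groups, taken from probe sets with 1 gene symbol that passed the threshold and whose groups did not overlap; 5 of each sign were taken where the lone Bdh2 array took part and for the departure from additivity. From each gene list past the threshold, the text draws on the 3 members with the smallest p in its direction and the 1 with the smallest p against it. Genes outside the rule are said to be chosen after their values were seen. Gene lists were tested with camera at a preset correlation of 0.01, two-sided, on 1 probe set per gene (the one with the highest mean over the arrays), adjusted over the 40 lists within a comparison; each list had at least 5 measured members. Camera with a correlation estimated from the residuals and fry were alternatives. The fry test asks whether the genes of a list move, on balance, in 1 direction and does not compare the list with other genes. Counts of members past the threshold are given over all probe sets and adjusted over the list alone.

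RNA quality was read from the 3 prime and 5 prime probe sets of the actin and GAPDH controls, with exact permutation tests, two-sided. Intervals of 95% around medians come from 10000 bootstrap draws of the genes or probe sets, not of the arrays. They hold no spread between samples. For pairs of comparisons against the same control arrays, 100 sets of unchanged groups were simulated with a simulated control group in common. Their noise was drawn independently for each probe set from its SD within groups, and the measured control values were not used as the control. The procedure was tested on simulated data before use: in Atg7 minus control, 82% of probe sets changed by 0.5 on the log2 scale and 100% of those changed by 1 were recovered, with 13 false calls among 195. For dual minus control these were 83% and 100%, with 8 false among 191, and for Bdh2 minus control 52% and 97%, with 7 false among 156. With no change put in, 0 probe sets and 0 of 40 lists were called in the Atg7 minus control layout. A shift of 0.3 put on the autophagy list alone was called. The simulated values were independent between probe sets, so this does not test the lists where their genes vary together.

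The alternatives tried were quantile normalization, a shift of each array to a common median, removal of the 40% of probe sets with the lowest mean (below 5.7, leaving 9301), an intensity trend with robust variance, array weights, the replicate number as a block, a 2-fold minimum, fits of only the groups compared, the mean of all probe sets of a gene, and leaving out each array in turn. Removal of probe sets with large changes shared by all arrays with the Bdh2 morpholino was added after seeing the data.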

Results

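Gene expression was profiled in zebrafish embryos in which Atg7, Bdh2 or both had been targeted by morpholinos. Atg7 is an enzyme needed to conjugate ubiquitin-like proteins during autophagosome formation. Bdh2 is a cytosolic dehydrogenase known for its part in making the mammalian siderophore, a small molecule that binds iron. Control, Atg7 and dual morphants had 3 arrays each and Bdh2 morphants had 1. The deposited log2 values covered 15502 probe sets after control probes were removed, and the array medians ranged from 6.32 to 6.38.

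Arrays of the same group were closest to each other. Pearson's r across probe sets was 0.998 to 0.999 among control arrays, 0.997 to 0.998 among Atg7 arrays and 0.997 to 0.998 among dual arrays. Between control and Atg7 arrays it was 0.994 to 0.996, and between control and dual arrays 0.985 to 0.988. The Bdh2 array correlated with dual arrays at 0.992 to 0.993 and with control arrays at 0.983. These correlations are across probe sets, which are not independent replicates. The 3 prime minus 5 prime difference of the actin control probe sets, a sign of RNA quality, was 3.45 ± 0.067 (SD, n = 3) in control arrays, 3.93 ± 0.11 (SD, n = 3) in Atg7 arrays, 3.86 ± 0.044 (SD, n = 3) in dual arrays and 4.30 in the Bdh2 array. By exact permutation test, which cannot go below 0.1 for 3 against 3, p was 0.1 for Atg7 against control (difference 0.47), 0.1 for dual against control (0.41) and 0.5 for dual against Atg7 (-0.064). The GAPDH differences were 1.58 ± 0.054, 1.67 ± 0.12 and 1.70 ± 0.026 (SD, n = 3 each) and 1.70 in the Bdh2 array.

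Of the targeted genes, bdh2 was read by 1 probe set, and no probe set was named atg7, so its transcript was not analysed here. bdh2 stood at 7.17 in control, 7.21 in Atg7, 7.28 in dual and 7.48 in Bdh2 morphants on the log2 scale. Its difference was 0.036 ± 0.072 in Atg7 minus control (adjusted p = 0.797), 0.11 ± 0.072 in dual minus control (adjusted p = 0.297) and 0.071 ± 0.072 in dual minus Atg7 (adjusted p = 0.496). In the lone Bdh2 array it was higher than in controls by 0.30 ± 0.10 (adjusted p = 0.0429), and this call ended without control replicate 1 (0.30, adjusted p = 0.0791) or control replicate 2 (0.25, adjusted p = 0.11). A morpholino that blocks translation need not lower its transcript, so these levels do not check the labels.

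The comparison of Atg7 with control morphants asked what follows from targeting Atg7 alone. Genes of acute inflammation rose and genes of red blood cells fell. The largest named rise was that of irf1b, an interferon regulatory factor, by 1.84 ± 0.068 on the log2 scale (3.58-fold, adjusted p = 3.57e-08). The matrix metalloproteinase genes mmp9 and mmp13a rose by 1.76 ± 0.066 and 1.49 ± 0.081, the AP-1 subunit genes fosab and junba by 1.71 ± 0.10 and 1.24 ± 0.067, and socs3a, a feedback inhibitor of cytokine signalling, by 1.5 ± 0.058. irg1l, rps27l, scamp5a and fn1b rose by 1.41, 1.27, 1.24 and 1.23. The largest named fall was that of slc4a1a, which encodes the band 3 anion exchanger of the red cell membrane, from 9.46 to 7.84 (-1.62 ± 0.061, adjusted p = 3.57e-08). The embryonic globin genes hbbe2, hbbe3 and hbae3 fell by 1.5, 1.42 and 0.88. alas2, the erythroid enzyme that starts heme synthesis, fell by 1.45 ± 0.075, the red cell carbonic anhydrase gene cahz by 1.04, and epb41b, which encodes a protein of the red cell membrane skeleton, by 0.87. The fin fold gene and2 fell by 1.05, hsp70.3 by 0.85 and hoxc13a by 0.82. The rule for naming these genes required all 3 Atg7 arrays to lie outside the range of the 3 control arrays, so that separation adds no evidence. Other probe sets of fosab were at 1.4, 0.44 and 0.53, and that of hbae3 at -0.68. The probe sets for irf1b, fosab, mmp13a, hbae3 and hsp70.3 carry suffixes that mark sequence shared with other transcripts.

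In total 1536 probe sets passed the threshold in Atg7 minus control, 971 higher and 565 lower, and 30 of them differed by at least 2-fold. Over all 15502 probe sets the groups did not overlap in 4707, where chance gives 10% for 3 against 3. The count was lower without any single array. It was 937, 811 and 902 without control replicates 1, 2 and 3, and 1011, 1072 and 1185 without Atg7 replicates 1, 2 and 3. Each removal also takes a residual degree of freedom, so these falls do not single out an array. With the replicate number as a block it was 1006.

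Of the 40 gene lists, 13 passed the threshold in Atg7 minus control. In the acute inflammation list 17 of 23 measured members rose and 0 fell (17 and 1 adjusted over the list alone), with a median of 0.55 (camera, adjusted p = 1.32e-17, and 0.00243 with an estimated correlation). In the erythroid and globin list 12 of 23 members fell and 0 rose (13 and 0 adjusted over the list alone; median -0.39, adjusted p = 3.05e-11, and 0.00461 with an estimated correlation). In the proliferation list 20 of 82 members fell, among them orc4 (-0.67), mcm7 (-0.44) and rrm1 (-0.42), which act in DNA replication or nucleotide supply, and 1 rose, ect2 (0.30). Adjusted over the list alone 37 fell and 1 rose (adjusted p = 2.02e-10, and 0.0246 with an estimated correlation). The neuron list had 9 of 49 members higher and 0 lower (10 and 0 adjusted over the list alone), with elavl3 at 0.50, islr2 at 0.40 and elavl4 at 0.38 (adjusted p = 3.03e-05, and 0.0246 with an estimated correlation).

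The autophagy list, in which atg7 itself was not counted, had 7 of 27 members higher and 1 lower (13 and 1 adjusted over the list alone; median 0.15, adjusted p = 0.000188, and 0.0266 with an estimated correlation). The autophagy receptor genes sqstm1 and nbr1a rose by 0.56 and 0.34 and bnip4 by 0.30, whereas pik3c3, which encodes the lipid kinase that acts at the start of the pathway, fell by 0.22. In the heat shock list 8 of 28 members fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.00112, and 0.038 with an estimated correlation). Among them were hsp70.3 at -0.85, st13 at -0.31, hsp90aa1.1 at -0.26 and hspb8 at 0.26. In the p53 response list 11 of 26 rose and 2 fell (12 and 4 adjusted over the list alone; adjusted p = 0.00314, and 0.0499 with an estimated correlation). Examples were rps27l at 1.27, phlda3 at 0.82, casp8 at 0.75 and rrm2b at -0.55.

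The other 6 lists lost their call with an estimated correlation. In the heme synthesis list 3 of 11 members fell and 0 rose (4 and 0 adjusted over the list alone; adjusted p = 0.00346, and adjusted p = 0.169 with an estimated correlation), namely alas2, which the erythroid list also holds, urod (-0.48) and cpox (-0.24). In the skin and fin epidermis list 16 of 44 rose and 4 fell (30 and 5 adjusted over the list alone; adjusted p = 1.82e-06, and adjusted p = 0.0842 with an estimated correlation). Members included pkp3a, evpla and anxa2a at 0.91, 0.62 and 0.59. In the lysosome list 5 of 42 rose and 1 fell (5 and 3 adjusted over the list alone; adjusted p = 0.0154, and adjusted p = 0.161 with an estimated correlation). Among them were the protease genes ctsba, ctsf and ctsd at 0.82, 0.42 and 0.31 and ctss2.1 at -0.25. A probe set with no gene symbol that shares the number in its name with that of ctsba, chosen after its values were seen, was at -0.61. In the pigment cell list 5 of 20 fell and 1 rose (5 and 1 adjusted over the list alone; adjusted p = 0.0154, and adjusted p = 0.355 with an estimated correlation). Examples were mitfa, a regulator of melanocyte development, at -0.64, gart at -0.42, slc2a15b at -0.34 and paics at 0.25. The lens list had 4 of 14 members higher and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 0.0256, and adjusted p = 0.473 with an estimated correlation). Members included the crystallin genes cryba4 and crygmxl2 at 0.99 and 0.76, and crybg1a, which entered the list by a pattern in its name, at 0.45. The ribosomal protein list had 2 of 81 members higher and 1 lower (1 and 1 adjusted over the list alone), with a median of -0.050 (adjusted p = 0.0229, and adjusted p = 0.161 with an estimated correlation), and its call also ended with quantile normalization (adjusted p = 0.856). The lens call ended without control replicate 1, Atg7 replicate 2 or Atg7 replicate 3 (adjusted p = 0.0841, 0.067 and 0.104), the lysosome and pigment cell calls without Atg7 replicate 1 (adjusted p = 0.0594 for both). Among the members named here, the calls of cpox, pik3c3, hspb8, ctss2.1, bnip4, st13 and paics each ended without some single array, with adjusted p between 0.0501 and 0.129. All of these lists stood beside an actin 3 prime minus 5 prime difference that was 0.47 higher in Atg7 than in control arrays.

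**Figure D1:**
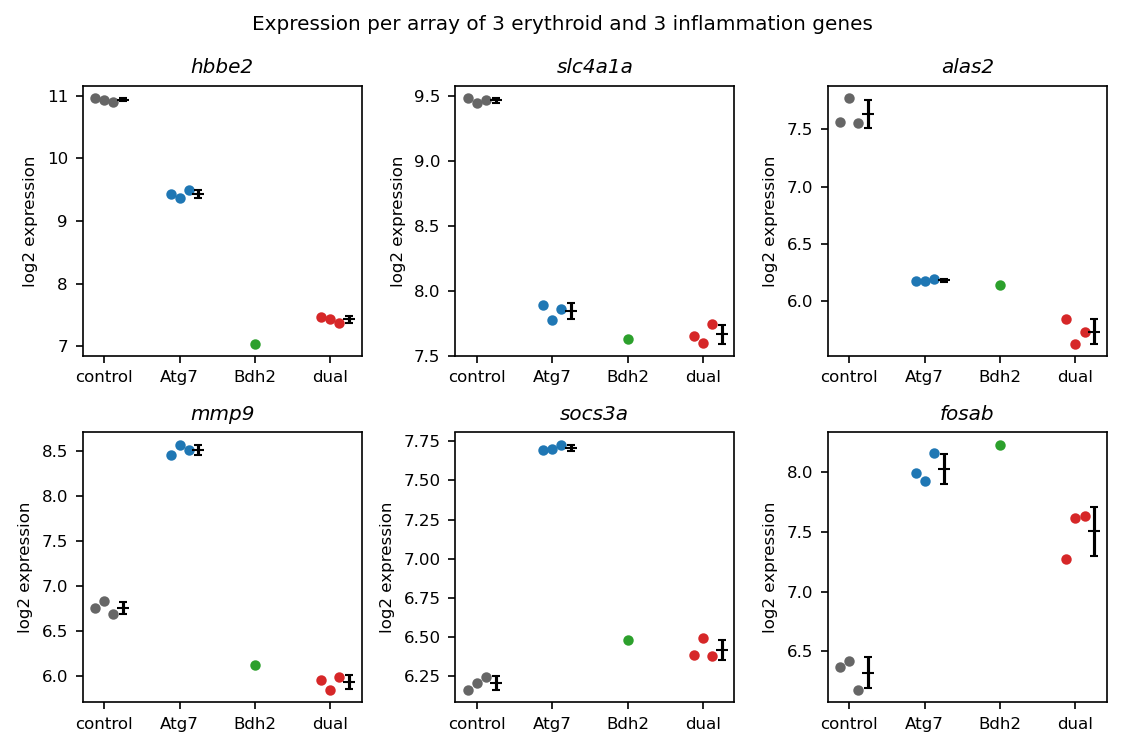
Log2 expression per array (y axis) in control, Atg7, Bdh2 and dual morphants (x axis) for the erythroid genes hbbe2, slc4a1a and alas2 and the inflammation genes mmp9, socs3a and fosab. Each point is 1 array, and bars show the mean and SD of 3 arrays where a group has them; hbbe2 averaged 10.9 in control, 9.43 in Atg7 and 7.43 in dual morphants, while mmp9 averaged 6.76, 8.51 and 5.92.

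The comparison of dual with control morphants asked what follows from targeting both genes. Red blood cell genes were lower, by more than in Atg7 morphants for some globins, and a set of single genes differed by very large amounts. hbbe2 fell by 3.51 ± 0.060 on the log2 scale (11.4-fold, adjusted p = 3.53e-12), slc4a1a by 1.80 ± 0.061 and hbae3 by 1.54 ± 0.057 in the probe set used for the lists. ddit4, a stress-induced inhibitor of mTOR signalling, fell from 8.23 to 4.19 (-4.04 ± 0.13, adjusted p = 8.38e-10). Also lower were frg1 (-3.35), calr (-3.34), lgals2b (-3.08), ahsa1a (-2.98), mhc1zba (-2.78), col10a1a (-2.69), acsl1a (-2.51) and epdl2 (-2.27). The largest named rises were those of rnf146 (2.91 ± 0.13), hsp70.3 (2.89 ± 0.067), mchr1b (2.80 ± 0.059) and ppiaa (2.70 ± 0.066), followed by ttn.2 (2.08), cyp26a1, a retinoic acid degrading enzyme (2.08 ± 0.081), cyp17a1 (1.98), farp2 (1.95), the lysosomal protease gene ctsba (1.88 ± 0.062) and parvaa (1.84). The rule for naming the largest changes required the 3 dual arrays to lie outside the range of the 3 control arrays.

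Other probe sets of the same gene did not always move with these. The other probe set was at 0.22 for calr, -0.17 for mchr1b, -0.037 for ppiaa and -0.20 for cyp17a1. rnf146 had others at 2.81 and -0.19, farp2 at 0.19 and 1.09, ttn.2 at 0.17, 0.11 and 1.64, and acsl1a at -0.25, -1.77, -0.48 and -0.031. A probe set with no gene symbol that shares the number in its name with that of ctsba moved the other way, at -5.93. It was chosen after its values were seen. Across the array, 155 probe sets (65 higher and 90 lower) differed by at least 2-fold in the same direction in dual minus Atg7 and in Bdh2 minus control, 30 of them by at least 4-fold in both, and in all 155 the 4 arrays with the Bdh2 morpholino lay on 1 side of the 6 without it. They held 9 of the 10 named rises of dual minus control, all but cyp26a1, and all 10 named falls. The farthest were a pair of probe sets with no gene symbol, at -8.83 and 7.61 in dual minus control, chosen after their values were seen.

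In dual minus control 5041 probe sets passed the threshold, 2582 higher and 2459 lower, and 232 differed by at least 2-fold. Over all 15502 probe sets the groups did not overlap in 7192, where chance gives 10%. Of the 40 lists 9 passed, and the erythroid and globin list was the 1 whose call held with an estimated correlation. In it 17 of 23 members fell and 1 rose, the carbonic anhydrase gene ca2 by 0.27 (18 and 1 adjusted over the list alone; median -0.51, adjusted p = 5.89e-08, and 0.0217 with an estimated correlation).

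The remaining lists of dual minus control lost their call with an estimated correlation, with adjusted p between 0.101 and 0.384. In the ATF4 target list 19 of 32 members fell and 3 rose (20 and 5 adjusted over the list alone; adjusted p = 0.000648, and adjusted p = 0.203 with an estimated correlation). In it ddit4, chac1 (-0.72) and the amino acid transporter subunit gene slc3a2a (-0.65) were lower and ppp1r15a (0.60) was higher. In the skeletal muscle list 19 of 48 fell and 3 rose (22 and 3 adjusted over the list alone; adjusted p = 0.000648, and adjusted p = 0.101 with an estimated correlation). Examples were the calcium pump gene atp2a1l at -1.81, pvalb5 at -1.14, ldb3a at -0.98 and tnni2b.1 at 0.39. In the glycolysis list 14 of 29 fell and 3 rose (15 and 3 adjusted over the list alone; adjusted p = 0.00576, and adjusted p = 0.203 with an estimated correlation). Members included pklr at -1.23, pfkma at -1.18, eno3 at -0.73 and tpi1a at 0.51. In the hypoxia list 11 of 23 fell and 2 rose (12 and 2 adjusted over the list alone; adjusted p = 0.0153, and adjusted p = 0.27 with an estimated correlation). Among them were igfbp1a at -0.86, higd1a at -0.77 and igfbp1b at 0.40. The proliferation list, lower in Atg7 morphants, had 29 of 82 members higher and 10 lower (29 and 10 adjusted over the list alone; adjusted p = 0.00647, and adjusted p = 0.203 with an estimated correlation). Examples were anln at 0.64, slbp at 0.54, lig1 at 0.51 and tk1 at -0.50. In the neuron list 16 of 49 rose and 7 fell (17 and 8 adjusted over the list alone; adjusted p = 0.00928, and adjusted p = 0.157 with an estimated correlation). Members included elavl3 at 1.11, atp1b2a at 0.55, gap43 at 0.52 and gng13b at -0.60. In the lens list 6 of 14 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 0.00647, and adjusted p = 0.384 with an estimated correlation). Among them were cryba4, crybb1 and crygmxl2 at 1.52, 1.34 and 0.76. In the proteasome list 13 of 46 rose and 3 fell (13 and 3 adjusted over the list alone; adjusted p = 0.047, and adjusted p = 0.203 with an estimated correlation). Examples were psmd11b at 0.47, psme2 at 0.37, psma1 at 0.30 and psmd10 at -0.54. The proteasome call ended without control replicate 1, control replicate 3, dual replicate 1 or dual replicate 2 (adjusted p = 0.062, 0.065, 0.0546 and 0.0601). The acute inflammation list was not past the threshold (6 rose and 6 fell, 6 and 8 adjusted over the list alone; median 0.048, mean -0.036, adjusted p = 0.77). In it fosab was higher by 1.19 and mmp13a and mmp9 were at -1.42 and -0.83. The actin 3 prime minus 5 prime difference was 0.41 higher in dual than in control arrays.

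**Figure D2:**
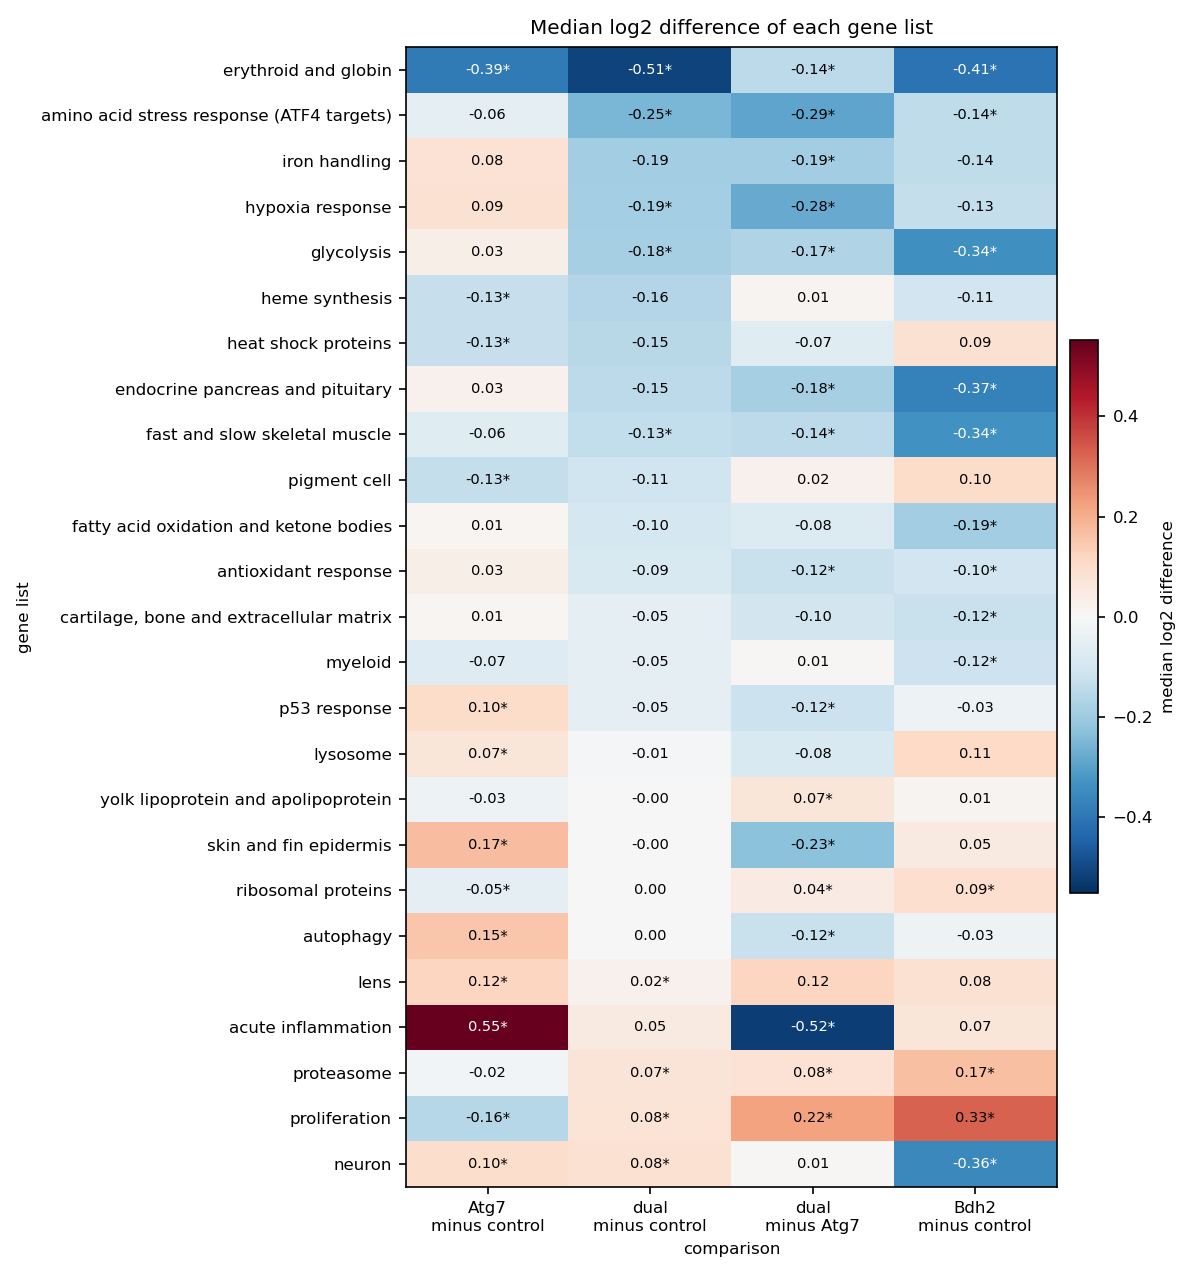
Median log2 difference of the members of each gene list (y axis) that passed the threshold in at least 1 of the 4 comparisons shown (x axis), coloured from blue (lower) to red (higher). A star marks an adjusted p below 0.05 by camera with the preset correlation; the erythroid and globin list is below 0 in all 4 comparisons, while acute inflammation is at 0.55 in Atg7 minus control and -0.52 in dual minus Atg7.

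The comparison of dual with Atg7 morphants asked what the Bdh2 morpholino does in embryos that also carry the Atg7 morpholino. Proliferation genes were higher and inflammation genes lower in dual than in Atg7 morphants. In the proliferation list 49 of 82 members rose and 3 fell (53 and 4 adjusted over the list alone; median 0.22, adjusted p = 1.29e-11, and 0.0333 with an estimated correlation). Members included the replication genes mcm5 and cdc6 both at 0.65, rrm1 at 0.63 and ccne1 at -0.63. In the acute inflammation list 15 of 23 fell and 1 rose (15 and 1 adjusted over the list alone; median -0.52, adjusted p = 4.28e-06, and 0.0333 with an estimated correlation). mmp13a fell by 2.91 ± 0.081, mmp9 by 2.59 ± 0.066 and socs3a by 1.29 ± 0.058, and saa rose by 0.30, a call that ended without Atg7 replicate 1 (0.19, adjusted p = 0.0679), dual replicate 2 (0.28, adjusted p = 0.0775) or dual replicate 3 (0.30, adjusted p = 0.0551). mmp13a and mmp9 were also among the 10 largest named falls.

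The remaining largest differences were again single-gene ones. hsp70.3 rose by 3.74 ± 0.067, mchr1b by 2.94, rnf146 by 2.73, ppiaa by 2.64, cyp17a1 by 2.03, farp2 by 1.96, tnpo2a by 1.95, parvaa by 1.90, rtkn2 by 1.86 and hnrnpa0a by 1.84. Lower were ddit4 (-3.86 ± 0.13), calr (-3.44), lgals2b (-3.43), frg1 (-3.36), mhc1zba (-2.97), col10a1a (-2.83), ahsa1a (-2.79) and epdl2 (-2.19). All 10 of these rises and 9 of the 10 named falls, all but mmp9, were among the 155 probe sets shared with Bdh2 minus control. Other probe sets of hnrnpa0a were at 0.12 and -0.0099, and that of calr at 0.073. In total 5115 probe sets passed the threshold in dual minus Atg7, 2448 higher and 2667 lower, 245 by at least 2-fold. With quantile normalization 2639 were higher and 2598 lower, so the balance of directions turned. Over all 15502 probe sets the groups did not overlap in 6844, where chance gives 10%.

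A further 14 lists passed in dual minus Atg7 and lost their call with an estimated correlation, with adjusted p between 0.12 and 0.203. Lower were ATF4 targets (23 of 32 fell and 4 rose; adjusted p = 0.12 with an estimated correlation), hypoxia genes (13 of 23 fell and 0 rose; adjusted p = 0.12 with an estimated correlation), skin and fin epidermis genes (26 of 44 fell and 4 rose; adjusted p = 0.134 with an estimated correlation) and muscle genes (22 of 48 fell and 4 rose; adjusted p = 0.12 with an estimated correlation). Adjusted over the list alone these were 24 and 4, 14 and 0, 26 and 4, and 24 and 4. The keratin genes krt15 and krt94 were at -1.51 and -1.33, anxa2a at -0.83, igfbp1a at -1.37 and atp2a1l at -1.37. In the iron handling list 7 of 16 fell and 1 rose (7 and 2 adjusted over the list alone; adjusted p = 0.00619, and adjusted p = 0.12 with an estimated correlation). Among them were the copper-dependent ferroxidase gene cp at -2.14 ± 0.062, the ferritin-like gene fthl28 at -1.06, the iron-responsive aconitase gene aco1 at -0.89 and the transferrin gene tfa at 0.40. The iron handling call ended when the 155 shared probe sets were left out (adjusted p = 0.0504), a setting chosen after seeing the data. In the erythroid and globin list 9 of 23 fell further and 0 rose (10 and 0 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). Examples were hbbe2 at -2.00, hbae3 at -0.86 and cahz at -0.85.

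In the autophagy list 9 of 27 fell and 2 rose (10 and 2 adjusted over the list alone; adjusted p = 0.0429, and adjusted p = 0.12 with an estimated correlation). Members included bnip3 at -0.97, bnip3lb at -0.87, sqstm1 at -0.49 and pik3c3 at 0.24. In the p53 response list 12 of 26 fell and 4 rose (13 and 4 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). Among them were rps27l at -1.82, casp8 at -1.49, phlda3 at -1.35 and ppm1da at 0.59. In the glycolysis list 13 of 29 fell and 3 rose (15 and 3 adjusted over the list alone; adjusted p = 0.122 with an estimated correlation), and in the endocrine pancreas and pituitary list 8 of 17 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). Examples were the hormone genes sst2, gcga and prl at -1.20, -1.08 and -0.89. The endocrine call also ended when the 155 shared probe sets were left out (adjusted p = 0.117). In the antioxidant list 12 of 33 fell and 3 rose (13 and 3 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). Members included ugdh at -0.79, gstt1a at -0.65 and nfe2l2a at 0.36. Higher were proteasome genes (11 of 46 rose and 1 fell; adjusted p = 0.122 with an estimated correlation), ribosomal protein genes (8 of 81 rose and 3 fell; adjusted p = 0.12 with an estimated correlation) and yolk lipoprotein and apolipoprotein genes (6 of 20 rose and 1 fell; adjusted p = 0.203 with an estimated correlation), the last with apom at 0.78, apoa4a at 0.52 and apoda.2 at -0.47. Adjusted over the list alone these were 10 and 1, 6 and 2, and 6 and 1. The calls of autophagy (adjusted p = 0.0741), antioxidant (0.0779) and yolk lipoprotein genes (0.0796) ended without Atg7 replicate 1. The autophagy call also ended without dual replicate 2 (adjusted p = 0.0505), and the antioxidant and yolk lipoprotein calls without dual replicate 1 (adjusted p = 0.0669 and 0.0618). Quantile normalization ended these 3 calls too (adjusted p = 0.0516 for each) and that of ribosomal protein genes (adjusted p = 0.249).

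The changes in Atg7 and dual morphants, both taken against the same control arrays, were set against each other across probe sets. Pearson's r was 0.264 and Spearman's rho 0.3, where simulated unchanged groups with a simulated control in common gave an r of 0.502. The covariance was 0.0162 against 0.00393 in the simulation, a difference of 0.0122. Of the probe sets past the threshold, 478 were higher in both and 257 lower in both, against 162 and 89.6 for independent lists, and 197 moved in opposite directions. Shared controls alone raise such counts. The share of all probe sets with the same sign was 61.5%, beside 66.7% in the simulated unchanged groups. The simulation holds no changed probe sets, whereas 1536 passed the threshold in Atg7 minus control and 5041 in dual minus control. Changes in 1 group alone lower r and the same-sign share, so of these values only the covariance can be set against the simulation. The simulated noise was independent between probe sets, so it holds no deviations of the control arrays that many probe sets share. The controls at 3 arrays could not be split into groups of at least 2.

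The lone Bdh2 array showed the nearest to a Bdh2 morpholino alone, with no replicate check. Proliferation genes were higher and red cell, muscle and neuron genes lower than in controls. In the proliferation list 53 of 82 members rose and 2 fell (56 and 2 adjusted over the list alone; median 0.33, adjusted p = 5.47e-11, and 0.0192 with an estimated correlation). Among them were chek1, lig1 and cdc6 at 0.93, 0.90 and 0.78. In the erythroid and globin list 13 of 23 fell and 0 rose (14 and 0 adjusted over the list alone; median -0.41, adjusted p = 1.09e-07, and 0.0135 with an estimated correlation). Examples were hbbe2 at -3.90 ± 0.085, slc4a1a at -1.84 and hbae3 at -1.48. In the skeletal muscle list 28 of 48 fell and 5 rose (29 and 6 adjusted over the list alone; adjusted p = 2.88e-07, and 0.0135 with an estimated correlation). Members included atp2a1l at -3.12, pvalb5 at -1.78, ldb3a at -1.64 and tnni2b.1 at 1.27. In the neuron list 26 of 49 fell and 2 rose (27 and 2 adjusted over the list alone; adjusted p = 1.62e-06, and 0.0135 with an estimated correlation). Among them were gng13b at -1.56, the synaptic gene snap25b at -1.23, stmn1b at -1.19 and cntn2 at 0.74. The actin 3 prime minus 5 prime difference of this array, 4.30, was the highest of the 10.

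The largest named rises in Bdh2 minus control were ppiaa (2.84), mchr1b (2.77), rnf146 (2.55), hsp70.3 (2.54) and cyp11a1.1, which encodes the enzyme that starts steroid synthesis (2.40 ± 0.14), and the largest named falls besides hbbe2 were ddit4 (-3.94), frg1 (-3.76), col10a1a (-3.72) and calr (-3.40). Of these 10 genes, 4 of the 5 rises, all but cyp11a1.1, and all 5 falls were among the 155 shared probe sets. In total 4376 probe sets passed the threshold, 2322 higher and 2054 lower (2216 and 2251 with quantile normalization), and 366 differed by at least 2-fold. Bdh2 minus control and dual minus Atg7, which share no array, correlated across probe sets at r = 0.736 (Spearman's rho 0.611), a comparison chosen after seeing the data. Of the probe sets past the threshold in each, 1247 were higher in both and 1282 lower in both, against 367 and 353 for independent lists, and 130 were opposite. The Atg7 effect without and with the Bdh2 morpholino, Atg7 minus control and dual minus Bdh2, which share no array either, correlated at r = 0.224 (Spearman's rho 0.264). In that pair 209 were higher in both and 99 lower in both, against 63.4 and 31.2 for independent lists, and 109 were opposite. Against the shared controls, dual and Bdh2 changes correlated at r = 0.779, with 0.354 in simulated unchanged groups, and the covariance was 0.107 against 0.00392.

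**Figure D3:**
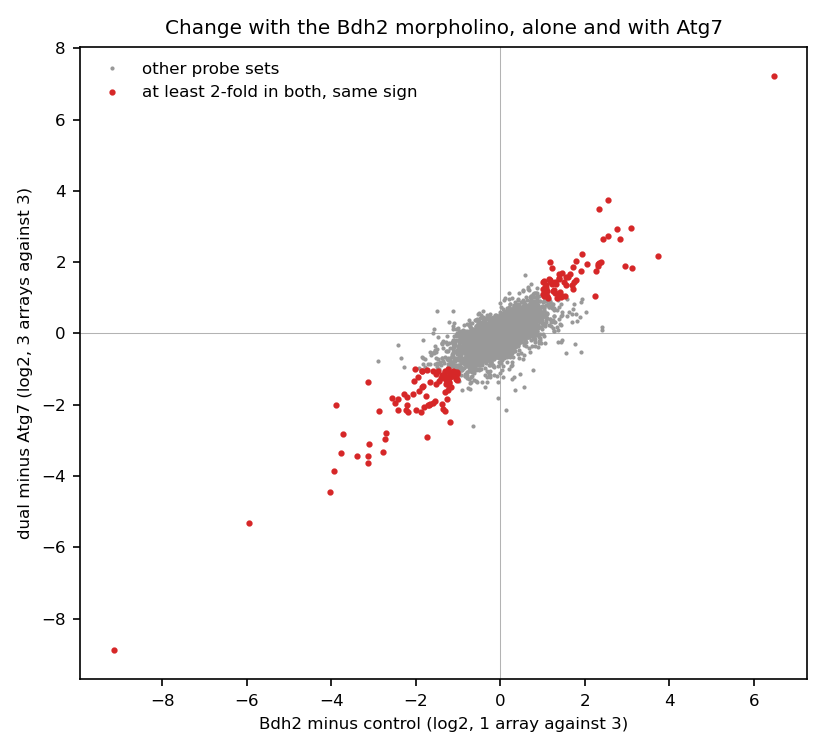
Log2 difference of each probe set in Bdh2 minus control (x axis, 1 array against 3) and in dual minus Atg7 (y axis, 3 arrays against 3). Red points are the 155 probe sets at least 2-fold in both with the same sign, grey points all others; r across all probe sets is 0.736.

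A further 9 lists passed in Bdh2 minus control and lost their call with an estimated correlation. Glycolysis genes were lower (16 of 29 fell and 0 rose, 18 and 1 adjusted over the list alone; adjusted p = 0.0714 with an estimated correlation). Examples were pfkma at -2.01, pklr at -1.40 and eno3 at -1.08. Endocrine pancreas and pituitary genes were lower (10 of 17 fell and 0 rose, 10 and 1 adjusted over the list alone; adjusted p = 0.0561 with an estimated correlation). Members included sst2, gcga and the insulin gene ins at -1.08, -1.06 and -0.97. So were cartilage, bone and matrix genes (18 of 49 fell and 6 rose, 18 and 6 adjusted over the list alone; adjusted p = 0.203 with an estimated correlation). Among them were runx3 at -1.13 and the collagen genes col1a1a and col14a1a at -0.73 and 1.24. ATF4 targets had 12 of 32 lower and 3 higher (12 and 3 adjusted over the list alone; adjusted p = 0.195 with an estimated correlation). Examples were chac1 at -0.94 and ppp1r15a at 0.89. Fatty acid oxidation and ketone body genes, the last a pathway to which cytosolic hydroxybutyrate dehydrogenases are tied, had 12 of 34 lower and 4 higher (12 and 4 adjusted over the list alone; adjusted p = 0.113 with an estimated correlation). Members included acadvl at -1.16, eci2 at -0.59, acadl at -0.57 and ech1 at 0.62. Antioxidant genes had 12 of 33 lower and 4 higher (14 and 6 adjusted over the list alone; adjusted p = 0.113 with an estimated correlation). Among them were the catalase gene cat at -1.25, gstt1a at -1.13, the superoxide dismutase gene sod2 at -0.94 and nfe2l2a at 0.67. Myeloid genes had 10 of 34 lower and 3 higher (13 and 4 adjusted over the list alone; adjusted p = 0.195 with an estimated correlation). Examples were mmp13a at -1.73, the lysozyme gene lyz at -0.97, the myeloperoxidase gene mpx at -0.85 and ctss2.1 at 0.53. Other probe sets of mpx were at 0.51, -0.19 and 0.18. Proteasome genes had 13 of 46 higher and 2 lower (13 and 2 adjusted over the list alone; adjusted p = 0.113 with an estimated correlation), and ribosomal protein genes 2 of 81 higher and 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.113 with an estimated correlation). The antioxidant call ended without control replicate 1 or 2 (adjusted p = 0.0502 and 0.0523), the ribosomal protein call with quantile normalization (adjusted p = 0.101) and the myeloid call when the 155 shared probe sets were left out (adjusted p = 0.0618).

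Dual morphants differed from the Bdh2 array in 1870 probe sets, 1013 higher and 857 lower, 78 of them by at least 2-fold. With array weights the count was 3063 and the balance turned (1451 higher and 1612 lower), and with the replicate number as a block it was 1144. The neuron list had 30 of 49 members higher in dual morphants and 0 lower (32 and 1 adjusted over the list alone; median 0.50, adjusted p = 6.26e-21, and 0.00127 with an estimated correlation). Members included islr2, stmn1b and rtn1b at 1.03, 0.93 and 0.83. Skeletal muscle genes (18 of 48 rose and 3 fell, 24 and 7 adjusted over the list alone; adjusted p = 2.99e-06, and 0.0212 with an estimated correlation) and hepatocyte genes (14 of 33 rose and 2 fell, 16 and 3 adjusted over the list alone; adjusted p = 2.99e-06, and 0.0212 with an estimated correlation) were higher too, the last with leg1.1, the clotting factor gene f5 and the fibrinogen gene fgb at 0.86, 0.77 and 0.74. Proliferation genes were lower (22 of 82 fell and 0 rose, 39 and 0 adjusted over the list alone; adjusted p = 1.13e-09, and 0.0284 with an estimated correlation). Among them were gmnn, cdca7a and rfc4 at -0.60, -0.53 and -0.47. The largest named rises were crx (2.40 ± 0.11) and vsx1 (2.12 ± 0.13), transcription factors of retinal cells, then lctla (1.68), pygl (1.6) and hsc70 (1.51). Other probe sets of pygl were at 1.32 and 0.66, and that of hsc70 at -0.15. The largest named falls were cyp11a1.1 (-2.20), the urate oxidase gene uox (-1.89), the protease genes ctsc (-1.77) and ctss2.1 (-1.49) and krt17 (-1.28). None of these 10 genes was among the 155 shared probe sets.

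A further 7 lists passed in dual minus Bdh2 and lost their call with an estimated correlation. Cartilage, bone and matrix genes (15 of 49 rose and 4 fell, 21 and 7 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation), glycolysis genes (7 of 29 rose and 1 fell, 10 and 1 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation), fatty acid oxidation genes (4 of 34 rose and 1 fell, 4 and 1 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation) and lens genes (4 of 14 rose and 0 fell, 6 and 0 adjusted over the list alone; adjusted p = 0.518 with an estimated correlation) were higher in dual morphants. Examples were col10a1a (1.04), pfkma (0.83), acaa2 (0.54) and crygmxl2 (1.44). Oxidative phosphorylation genes passed as higher with 0 of 79 members rising and 1 falling, sdhaf2 by 0.34 (0 and 0 adjusted over the list alone; median 0.043, adjusted p = 0.0397, and adjusted p = 0.552 with an estimated correlation). Heat shock genes (5 of 28 fell and 2 rose, 7 and 3 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation) and ribosomal protein genes (2 of 81 fell and 0 rose, 2 and 0 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation) were lower, with hspb1 at -1.10, hspa8b at -0.92, hsp90aa1.1 at -0.58 and rps27l at -0.49. The oxidative phosphorylation and heat shock calls ended without dual replicate 1 (adjusted p = 0.0611 for both) or dual replicate 2 (adjusted p = 0.0733 and 0.0674). With quantile normalization they ended as well (adjusted p = 0.0934 and 0.053), as did that of ribosomal protein genes (adjusted p = 0.237).

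The departure from additivity asked whether the effects of both morpholinos together were the sum of their effects alone on the log2 scale. It passed the threshold in 1261 probe sets, 591 positive and 670 negative, and in 10 lists. With quantile normalization 716 were positive and 630 negative, and with a common median 677 and 560, so the balance of directions turned. The count was 1909 with array weights and 708 with the replicate number as a block. For the proliferation list it did not pass (0 positive and 3 negative of 82, adjusted p = 0.164). For acute inflammation genes it was negative in 15 of 23 members and positive in 0 (15 and 1 adjusted over the list alone; adjusted p = 7.41e-10, and 0.00667 with an estimated correlation). Examples were mmp9 at -1.95 ± 0.11, junba at -1.80 and socs3a at -1.57. For erythroid genes it was positive in 9 of 23 and negative in 0 (9 and 0 adjusted over the list alone; adjusted p = 3.87e-08, and 0.00799 with an estimated correlation). Members included hbbe2 at 1.89, slc4a1a at 1.66 and hbbe3 at 0.88. slc4a1a averaged 9.46 in control, 7.84 in Atg7 and 7.66 in dual morphants and was 7.62 in the Bdh2 array, so that the level with both morpholinos lay close to that with either. Neuron (20 of 49 positive and 1 negative, 28 and 1 adjusted over the list alone; adjusted p = 1.34e-12, and 0.0054 with an estimated correlation), skeletal muscle (14 of 48 positive and 4 negative, 25 and 5 adjusted over the list alone; adjusted p = 7.82e-08, and 0.00865 with an estimated correlation) and hepatocyte lists (9 of 33 positive and 1 negative, 10 and 1 adjusted over the list alone; adjusted p = 3.04e-05, and 0.0145 with an estimated correlation) were also positive. Cartilage, bone and matrix genes (9 of 49 positive and 5 negative, 13 and 6 adjusted over the list alone; adjusted p = 0.401 with an estimated correlation) and glycolysis genes (5 of 29 positive and 0 negative, 10 and 2 adjusted over the list alone; adjusted p = 0.139 with an estimated correlation) were positive with the preset correlation. Lysosome genes (5 of 42 negative and 0 positive, 7 and 0 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation), p53 response genes (7 of 26 negative and 1 positive, 10 and 1 adjusted over the list alone; adjusted p = 0.107 with an estimated correlation) and skin and fin epidermis genes (10 of 44 negative and 5 positive, 17 and 6 adjusted over the list alone; adjusted p = 0.405 with an estimated correlation) were negative. The skin call ended without Atg7 replicate 1, dual replicate 1 or dual replicate 2 (adjusted p = 0.0965, 0.0818 and 0.0604), and the cartilage call without dual replicate 3 (adjusted p = 0.0724). All of these values rest on the lone Bdh2 array, whose actin 3 prime minus 5 prime difference, 4.30, was the highest. They also assume that dual embryos received each morpholino at the dose of the single injections, which was not settled here.

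The other 13 lists passed in no comparison. In dual minus control, members that rose and fell numbered 2 and 3 of 20 for interferon response, 4 and 12 of 37 for the unfolded protein response, 1 and 6 of 14 for cholesterol synthesis, 1 and 2 of 21 for exocrine pancreas, 0 and 7 of 24 for intestine, 2 and 4 of 42 for photoreceptors, 3 and 4 of 16 for heart, 6 and 2 of 19 for glia and myelin, 2 and 3 of 13 for ionocytes, 5 and 7 of 25 for endothelium, 4 and 10 of 33 for apoptosis, 5 and 5 of 29 for the circadian clock and 1 and 5 of 7 for the hatching gland. In Atg7 minus control the counts for interferon response were 5 and 0, and for the unfolded protein response 0 and 6.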

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

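The tests of RNA quality, for both patterns below, and of the p53 response were chosen after the results they measure were seen. The effect of the Atg7 morpholino differed with and without the Bdh2 morpholino, by a test of the difference itself, in 1261 probe sets. The named genes with the most positive difference were and2 (2.13), pygl (2.11), crx (2.1), hbbe2 (1.89) and atp2a1l (1.75), and those with the most negative were fosab (-2.43), cyp11a1.1 (-2.29), uox (-2.11), cyp24a1 (-2.06) and mmp9 (-1.95), all on the log2 scale. Other probe sets were at 1.74 and 0.91 for pygl, at -2.05, -0.65 and -1.11 for fosab and at -0.27 for cyp24a1. By list, the median differences were 0.27 for erythroid and globin, 0.38 for neuron, 0.29 for skeletal muscle, 0.22 for hepatocyte, 0.15 for cartilage, bone and matrix and 0.14 for glycolysis genes, and -0.54 for acute inflammation, -0.18 for skin and fin epidermis, -0.16 for p53 response and -0.15 for lysosome genes. All rest on the lone Bdh2 array.

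The inflammation list rose in Atg7 morphants and, as a list, not in dual morphants, where 6 of 23 members rose and 6 fell; fosab was higher than in controls in dual morphants (1.19) and in the Bdh2 array (1.91) as well. A loss of RNA quality acting alone would raise the list in both, since the actin 3 prime minus 5 prime difference was higher by 0.47 and 0.41. The GAPDH difference was higher by 0.081 and 0.11, so the size of any loss depends on the control used. The list's median was 0.55 (95% interval 0.34 to 0.74) in Atg7 minus control and 0.048 (-0.19 to 0.14) in dual minus control. That argues against RNA quality as the sole cause, though the contrast is the pattern itself and no separate test. A rise from RNA quality that the Bdh2 morpholino or its clutch offset in dual morphants stays open. More myeloid cells would raise the other myeloid genes, but 0 of the 30 outside the inflammation list rose and 8 fell. Their median was -0.078 (-0.24 to -0.035), which argues against more myeloid cells. All these intervals resample genes and not arrays. A response to the amount of morpholino acting through p53 would leave p53 genes at least as high in dual as in Atg7 morphants. This holds only if dual embryos received more morpholino. The p53 list was lower, with a median of -0.12 in dual minus Atg7, where 12 of 26 members fell and 4 rose. There fry (adjusted p = 1.38e-06) and camera with the preset correlation (adjusted p = 0.0432) passed. Camera with an estimated correlation, which the rule for this test also required, did not (adjusted p = 0.12), so this response stays open. That the Bdh2 morpholino may lower an inflammatory response to the Atg7 morpholino is the hypothesis the design offers, and a difference between clutches stays open beside it, untested.

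The Bdh2 array had lower neuron, muscle and hepatocyte genes and higher proliferation genes than dual morphants. RNA quality as the whole cause is argued against by the neuron list, which was higher in Atg7 minus control (median 0.098) although the actin difference was higher there too. The GAPDH difference was higher there by 0.081 (exact permutation test, p = 0.4), so this argument rests on actin. The muscle list had 7 of 48 members lower and 2 higher there (median -0.065, camera adjusted p = 0.0541), the direction RNA quality would give. The hepatocyte list had 5 of 33 higher and 4 lower. RNA quality thus stays open for muscle genes, and an Atg7 effect that offset it in neuron genes was not tested. A younger stage of the Bdh2 embryos may explain the pattern, and it might raise tailbud and segmentation genes in that array. Whether these genes still change with stage near 72 h was not tested, so they may miss a small delay. Their median in dual minus Bdh2 was -0.12, with 1 of 47 rising and 4 falling, but p was 0.304 by camera with an estimated correlation, so this stays open. An effect of the Bdh2 morpholino that the Atg7 morpholino offsets also stays open, untested, since there is 1 array.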

How the results depend on the processing

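The settings that leave out the shared probe sets were chosen after seeing the data; the others were planned. Under quantile normalization, the common median, the filter on dim probe sets, the intensity trend and fits of only the groups compared, every count of probe sets and of lists stayed within 1.5 times its value. The majority of rises in Atg7 minus control (63.2% of calls) was 55.8% with quantile normalization and 53.3% with the common median. The balance of directions turned with quantile normalization in dual minus Atg7 (2639 higher, 2598 lower), Bdh2 minus control (2216, 2251) and the departure from additivity (716, 630), with the common median in dual minus Atg7 (2962, 2309) and the departure from additivity (677, 560), with the dim filter in dual minus control (2109, 2230) and Bdh2 minus control (1950, 1981), with array weights in dual minus Bdh2 (1451, 1612), and with the 2-fold minimum in dual minus control (115, 117) and Bdh2 minus control (159, 207). The dim filter, which leaves fewer genes to test, ended 10 list calls: in dual minus Atg7 autophagy (adjusted p = 0.269), p53 response (0.177) and antioxidant response (0.0986), in Bdh2 minus control fatty acid oxidation (0.12), antioxidant response (0.0712) and myeloid (0.0588), in dual minus Bdh2 heat shock and oxidative phosphorylation (0.138 each) and in the departure from additivity p53 response (0.0846) and skin (0.0705). Array weights raised dual minus Bdh2 to 3063 and the departure from additivity to 1909. The replicate numbers did not pair the arrays: same-numbered arrays deviated together at r from -0.374 to 0.197, with 2 of 9 pairs over 0.1, and 0 of 9 arrays was closest to its own number. With the replicate block, counts were 1006 for Atg7 minus control, 1144 for dual minus Bdh2 and 708 for the departure from additivity, and bdh2 in Bdh2 minus control was 0.26 (adjusted p = 0.139). The block, which takes degrees of freedom, also ended 7 list calls: proteasome in dual minus control (0.0522), p53 response, antioxidant response and yolk lipoprotein in dual minus Atg7 (0.0507, 0.0507 and 0.0538), heat shock in dual minus Bdh2 (0.0901), and cartilage and skin in the departure from additivity (0.0504 each). It ended the calls of cpox (0.0735) and pik3c3 (0.071) in Atg7 minus control, which also ended with only 2 groups in the fit (0.0659 and 0.0605). With the lone Bdh2 array, it ended those of rps15 and psmd10 in Bdh2 minus control and of camk2d1 in the departure from additivity. The rps15 and camk2d1 calls also ended with quantile normalization, and that of camk2d1 with the common median and the intensity trend. All 3 ended without some single array as well. Other list calls ended in dual minus Atg7 for autophagy with the intensity trend (0.0524), antioxidant response and yolk lipoprotein with array weights (0.0626 and 0.0596), yolk lipoprotein with only 2 groups in the fit (0.0515) and autophagy and antioxidant response with the mean of all probe sets (0.0557 each). The same held in Bdh2 minus control for myeloid with the trend (0.0583) and antioxidant response with quantile normalization (0.0627), and in dual minus Bdh2 for heat shock with the mean of all probe sets (0.0774). A 2-fold minimum left 30, 232, 245, 366, 78 and 123 probe sets in Atg7 minus control, dual minus control, dual minus Atg7, Bdh2 minus control, dual minus Bdh2 and the departure from additivity, and did not pass bdh2 (0.30). In that order, lists past the threshold fell from 13, 9, 16, 13, 11 and 10 to 7, 1, 2, 4, 4 and 5 with an estimated correlation and came to 25, 32, 31, 33, 20 and 22 with fry, which asks another question. Without the 155 shared probe sets, counts were 1491, 4863, 4934, 4187, 1830 and 1219.

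Leaving out each array in turn gave 811 to 1185, 4104 to 4641, 4056 to 4595, 3610 to 4029, 1382 to 1763 and 859 to 1231 probe sets, and 13 to 17, 8 to 11, 14 to 18, 12 to 15, 9 to 12 and 9 to 11 lists. The bdh2 difference ranged from -0.014 to 0.086, 0.053 to 0.16, 0.017 to 0.12, 0.25 to 0.35, -0.25 to -0.14 and -0.29 to -0.18, and was negative (-0.014) in Atg7 minus control without control replicate 2; the cause was not tested. The correlation of Atg7 and dual changes ranged from 0.243 to 0.291. The lone Bdh2 array could not be left out, and pseudocounts were not run because the values are log2. Apart from bdh2, no named gene (327 results) and no list past the threshold (72) reversed in any setting run. Signal over background was not used, so how far dim probe sets limit these results is open.

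Other splits of the 6 arrays were too few (10) for a share under 0.05. The real split gave 1536, 5041 and 5115 probe sets in Atg7 minus control, dual minus control and dual minus Atg7, the highest of the others gave 0 in each, and 1 of 10 splits, the real one, reached the real value.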

Other observations

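The tests of sister probe sets, of RNA quality and of the arrays with the Bdh2 morpholino were chosen after the large shared changes were seen, as was the idea of a retinoic acid response, though not the values of its other target genes. Genes of retinoic acid signalling, in no list fixed at the start, were higher in Atg7 and dual morphants. cyp26a1, which degrades retinoic acid, rose by 1.2 ± 0.081 in Atg7 minus control, 2.08 in dual minus control and 1.91 in Bdh2 minus control, and dhrs3a, which lowers retinoic acid supply, by 1.01 ± 0.089, 0.86 and 0.80; both were chosen after their values were seen. A wider retinoic acid response may go with them. Of 24 other target genes, listed before their values were examined, 7 rose and 0 fell in Atg7 minus control (median 0.15, camera p = 2.52e-06, and 0.00548 with an estimated correlation), among them hoxb5b (0.60), hoxb6b (0.55), hoxd4a (0.45), hoxb5a (0.45) and cyp26b1 (0.39). In dual minus control 14 rose and 1 fell (median 0.34, p = 3.04e-06, and 0.0057 with an estimated correlation), and in Bdh2 minus control 8 rose and 3 fell (p = 0.00901, and 0.0572 with an estimated correlation). Several are Hox genes of the same cluster and are not independent, and a difference in patterning was not tested. Tailbud and segmentation genes, used here for stage, had 1 of 47 rising and 1 falling in Atg7 minus control (median -0.10). In dual minus control they had 2 rising and 8 falling (median -0.010), and neither comparison passed with camera. Whether these genes still change with stage near 72 h was not tested, so a difference in stage stays open. RNA quality stays open too, untested for these genes. The actin 3 prime minus 5 prime difference was higher in the same comparisons (0.47 in Atg7 minus control, 0.41 in dual minus control). That of GAPDH was higher by 0.081 and 0.11. In dual minus Atg7, where the actin difference was -0.064, the targets did not pass (7 rose and 3 fell, camera p = 0.132 with an estimated correlation). Both groups carry the Atg7 morpholino, so that outcome would also follow from an Atg7 effect and does not separate these causes.

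The 155 probe sets whose group means differed by at least 2-fold in the same direction in dual minus Atg7 and in Bdh2 minus control might reflect the genetic background of the clutches and not the morpholino. RNA quality as the whole cause is argued against: 178 probe sets at least 2-fold in Bdh2 minus control and in dual minus control, 138 of them among the 155 and chosen without the Atg7 arrays, had a median of 0.048 in Atg7 minus control in that direction (95% interval -0.0055 to 0.10), beside 1.51 in dual minus control, although the actin difference was as high (46 of them passed the threshold in that direction). Haplotype blocks that differ between clutches would place such genes side by side, and 5 neighbouring pairs were found among 98 genes against a median of 1 in 10000 permutations of the genes (permutation test, one-sided, p = 0.0044), but krt94 and krt15 are related tandem copies that could change or cross-hybridize together, which would not account for pairs that moved in opposite directions, such as cfp (1.19 in dual minus Atg7) and its neighbour (-3.11). A sequence difference read by single probe sets would leave other probe sets of the gene behind. Of 49 such probe sets, 14 followed (28.6%) against 9 of 17 (52.9%) for other 2-fold changes (Fisher's exact test, p = 0.0834). Some that followed, such as those of rnf146, slc25a14 and acsl1a, differ in name from the stepping probe set only by an x_at suffix. They may read the same sequence, and probe sets of the same gene are not independent. The test therefore cannot decide, and this stays open. All 155 separated the 4 arrays with the Bdh2 morpholino from the 6 without, which their choice nearly fixes and which adds no evidence; by the design, the morpholino and a clutch used for those injections cannot be told apart.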
